A study of Homo sapiens with 6 samples.

How the data were processed

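Total RNA of AF22 human neural stem cells was made into directional RNA sequencing libraries, per the labels' protocols, and 6 libraries were analysed, 3 control and 3 knockdown. Groups and library numbers were taken from the sample titles. The authors deposited 1 table per library with a gene symbol and a whole-number read count in each of 26485 lines; the values are raw counts, judged from the values, which are whole and sum to a different total in each library. Trim Galore 0.6.6, STAR 2.7.10a, bedtools and the hg38 build are named in the submitters' processing notes. The program that counted reads, its annotation and its strand setting are not given in the sources used here. Reads of overlapping genes, antisense pairs, near-identical copies and read-through transcripts could therefore have been split or dropped in ways that the counts do not show. Symbols are of an older annotation: of 920 list genes 906 were found in the files, 59 of them under an older symbol. No gene of the mitochondrial genome was matched, so that list was not analysed here.

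Total counts ran from 4962745 to 9640349 per library. The counts allow tests of genes above the filter only, and low genes carry large errors. No 2 libraries of a group agreed within sampling noise: the chi-square per gene between them, over genes with at least 20 counts in the pair, was at least 3.19. The 3 comparisons of knockdown library 2 with the control libraries gave 16.7 to 24.0.

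Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with its default settings (12937 genes), scaled with TMM factors and tested with the quasi-likelihood test (glmQLFit and glmQLFTest) with group as the only term. P-values were adjusted with the Benjamini-Hochberg method, at a threshold of 0.05. The SE of a log2 fold change was taken as its size divided by the square root of the F statistic. CPM values use the TMM-scaled totals, and log2 CPM values a prior count of 2. Gene lists were tested with camera (limma 3.58.1) on log2 CPM, with a preset inter-gene correlation of 0.01, two-sided and adjusted over 30 of 33 lists; the target locus list was handled apart. The lists, the unpaired design, the alternatives and the rule for named genes were fixed before the data were examined.

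The labels give both groups the numbers 1 to 3, and nothing says that a number marks a shared day or culture. Over the tested genes, the deviations from the group mean of same-numbered control and knockdown libraries correlated at 0.563, 0.467 and 0.535, across genes, which are not independent replicates. Every same-number correlation was above 0.1, the bound fixed beforehand, so the numbers were taken to pair the libraries, and the pairing comes from the data. This check and the calls of both fits were first seen in the same output. The paired fit, listed beforehand as an alternative, adds the number as a block.

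Named genes were those of the target locus with CDKN2A and CDKN2B; the 8 higher and 8 lower genes of largest log2 fold change and the 4 of smallest adjusted p, among genes past the threshold, with a mean of at least 1 CPM and no overlap between groups; and up to 4 members per list with the smallest p. The parts that need a gene past the threshold gave none in the unpaired fit. Applying them to the paired fit was chosen after the data were seen. Some members that the rule names are not reported here.

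Alternatives were RLE size factors, total count only, no filter, at least 1 CPM in 3 libraries, DESeq2 1.42.0, limma voom, an adjusted p of 0.01, a minimum log2 fold change of 1, leaving out each library, an estimated correlation in camera, and fry. Added for the paired fit after seeing the data were the same settings, leaving out each pair, thinning every library to the smallest total, and removing a trend with GC content and transcript length. GC and length came from GENCODE 29 transcripts (GRCh38) and were found for 94.9% of tested genes. The pipeline was tested on simulated counts for 12937 genes with 100 genes changed at each of 2 sizes and a further list of 40 genes lowered by 0.6 log2 units, in 1 draw for knockdown against control. The simulated means held effects of the library number, and the spread was that of the paired design. Without the block, 18% of the 100 genes changed by 0.6 log2 units and 85% of those changed by 1.5 were recovered. With it the shares were 73% and 100%, and 30 of the 40 list genes were recovered, with 14 of 217 calls false (6.45%). The gain with the block was thus built into the simulation and is no evidence that the real libraries are paired.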

Results

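RNA was sequenced from AF22 cells, an established human neural stem cell line, in 2 groups of 3 libraries each. The control group is labelled as a control for short hairpin RNA, and in the knockdown group BMI1 and COMMD3-BMI1 were the stated targets. BMI1 is a subunit of Polycomb repressive complex 1, and COMMD3-BMI1 is the annotated read-through of BMI1 and its upstream neighbour COMMD3. The files held whole read counts for 26485 gene symbols. Total counts were 5496683, 6387898 and 6870122 in control libraries 1, 2 and 3, and 4962745, 7304714 and 9640349 in knockdown libraries 1, 2 and 3. The labels call the 3 libraries of a group replicates by number, without saying whether they came from separate cultures. The p-values of single genes therefore measure the spread between these libraries, which may be technical. Those of gene lists with the preset correlation, and those of 3' UTR sequences, rest on the spread over genes. They take genes as nearly or fully independent, and are too small where genes move together. Libraries with the same number deviated together from their group means, and results are therefore also given from a paired fit with that number as a block. Knockdown library 2 stood apart from the rest, at 40.2 on the first principal component (49.2% of the variance), where the other 5 libraries lay between -25.5 and 11.5. Knockdown library 1 lay at -12.4, within the range of the control libraries (-25.5 to -4.1). Its chi-square per gene was 2.74 against control library 1, and 6.31 and 5.44 against control libraries 2 and 3. Any 2 libraries of the same group gave at least 3.19. This measure grows with the counts, and knockdown library 1 and control library 1 have the smallest totals and share a number. The value of 2.74 therefore does not show that they are closer than libraries of a group.

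The first question was whether the targeted locus was lowered. BMI1 fell to 32.8% of the control level, from 87.5 ± 2.44 to 29.2 ± 9.57 CPM (counts scaled by library size; mean ± SD, n = 3 each). Its counts were 463, 582 and 606 in the control libraries and 193, 159 and 250 in the knockdown libraries. The log2 fold change of BMI1 was -1.61 (SE 0.194), with an adjusted p of 5.04e-05 in edgeR's quasi-likelihood test adjusted over the list alone (the target locus genes). Adjusted over all 12937 genes tested, the p of BMI1 was 0.163, and in the paired fit it was 0.00836 with a log2 fold change of -1.64 (SE 0.155). The log2 differences within pairs 1, 2 and 3 were -1.09, -2.05 and -1.73. COMMD3, an endosomal sorting factor, was at 26.3 ± 2.06 CPM in control and 32.5 ± 0.873 CPM in knockdown libraries. Its log2 fold change was 0.31 (SE 0.11), with an edgeR adjusted p of 0.0230 over the list alone and 0.288 over all genes (0.0804 in the paired fit). COMMD3 lies on chromosome 10 at 22315974 to 22320308 and BMI1 at 22321211 to 22331484, both on the plus strand (GRCh38, GENCODE 29). The read-through COMMD3-BMI1, at 22316388 to 22329542, shares exons with both. It was listed at 0 counts in all 6 libraries, as were 34 of the 120 read-through symbols in all libraries. The counts do not show whether it was absent or its reads were counted elsewhere, so those of BMI1 and of COMMD3 may include them.

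**Figure D1:**
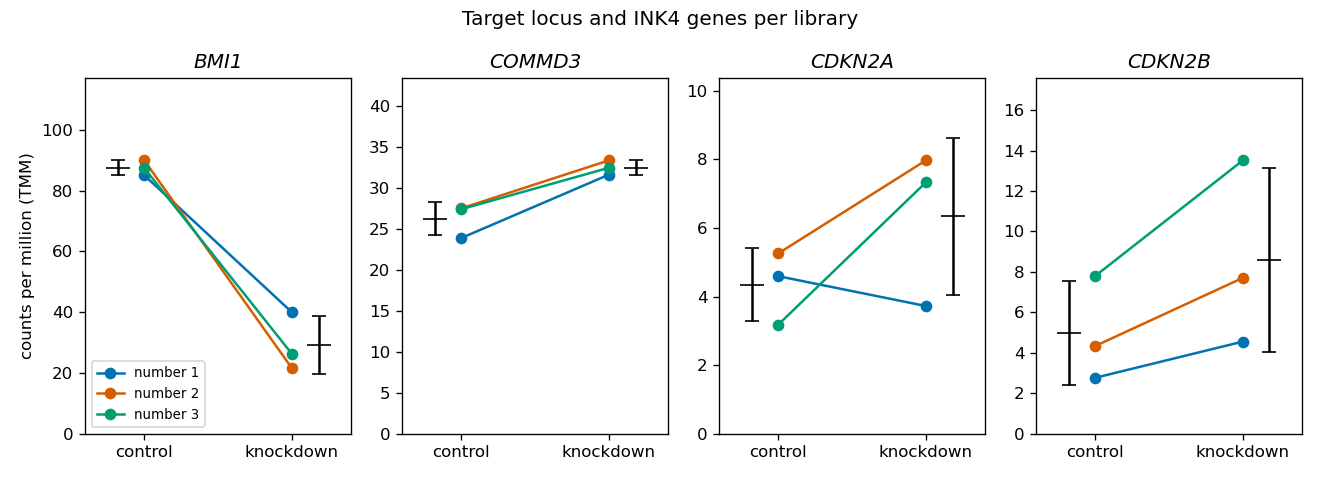
CPM (TMM-scaled, y axis from 0) of BMI1, COMMD3, CDKN2A and CDKN2B in each library, with lines joining control and knockdown libraries of the same number and black marks giving mean ± SD (n = 3). BMI1 lay at 85.1 to 90.0 CPM in control and 21.5 to 39.9 CPM in knockdown libraries, while the groups overlapped for CDKN2A and CDKN2B.

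Across the transcriptome, the unpaired edgeR test called 0 of 12937 genes at an adjusted p of 0.05. The smallest adjusted p was 0.163, and 1869 genes had an unadjusted p under 0.05, where chance gives 646.85. Unpaired DESeq2 called 150 genes (65 higher and 85 lower in knockdown) with 1587 at an unadjusted p under 0.05, and limma voom called 0. Without knockdown library 1 the unpaired edgeR test called 665 genes. The paired edgeR fit called 1296 genes, 599 higher and 697 lower in knockdown, and 77 of these changed at least 1 log2 unit (55 higher, 22 lower). Of the 1296 genes, 1295 moved in the same direction in all 3 pairs, and the groups did not overlap in 882. The paired test selects genes whose pairs agree, so the count of 1295 is no separate evidence of a shared change. Over all genes tested, the groups did not overlap in 20.5%, where chance gives 10% on average. Because genes move together, a single split of the libraries can lie far from this average, or from 646.85 genes, without a group effect. The share was not computed for other splits, so it is no test of the groups. Without pair 2 the paired fit called 2296 genes (1198 higher, 1098 lower), with fewer libraries left to measure the spread. That larger count is therefore no stronger evidence. Paired DESeq2 called 592. The balance of higher and lower genes also turned with a GC content and length trend removed (895 and 771), and it was 494 and 789 with total count scaling.

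The largest changes in the paired fit were as follows. KIT, a receptor tyrosine kinase, rose from 8.98 ± 1.09 to 28.6 ± 13.9 CPM (mean ± SD, n = 3 each; 3.16-fold, edgeR adjusted p 0.0187). UNC5D, a netrin receptor, rose 3.38-fold, the calcium channel subunit gene CACNA1D by 1.48 on the log2 scale, and the secreted glycoprotein gene STC1 2.68-fold. CCDC129 rose by 1.77, PCED1B by 1.61, FAM84A by 1.54 and CARD8-AS1 by 1.51 on the log2 scale. CCDC129, UNC5D, PCED1B, CARD8-AS1 and CACNA1D had a mean of at most 5.44 CPM in each group. PCED1B shares exon sequence with AMIGO2 and CACNA1D with CHDH on the opposite strand, and CARD8-AS1 is annotated as antisense to CARD8; the strand setting of the counting was not given, so these values are uncertain. After BMI1, the largest fall was that of the neuropeptide gene NMB, which fell by 1.41 on the log2 scale. B3GALNT1, a glycosyltransferase gene, fell from 16.3 ± 2.42 to 6.24 ± 1.19 CPM, a log2 fold change of -1.40 (SE 0.198, n = 3 each, edgeR adjusted p 0.0211). OAS3, an interferon-induced synthetase, changed by -1.18, HTATIP2 by -1.17, the mitotic gene CDCA3 by -1.15 and ZNF788 by -1.12 on the log2 scale. APITD1, which encodes a centromere protein, changed by -1.31, but it had 88 counts in all and shares its sequence with the read-through APITD1-CORT, which had 700. B3GALNT1 overlaps NMD3, CDCA3 overlaps GNB3 and ZNF788 overlaps ZNF20, each on the opposite strand.

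The smallest p-values beside BMI1 among genes whose groups did not overlap belonged to TNFRSF11B, ICAM1 and THOP1. TNFRSF11B, the decoy receptor osteoprotegerin, rose from 71.1 ± 3.54 to 126.5 ± 20.3 CPM (mean ± SD, n = 3 each). ICAM1, an adhesion molecule, rose from 89.6 ± 13.9 to 162.7 ± 43.9 CPM. Both had an edgeR adjusted p of 0.00836 in the paired fit. THOP1, a peptidase gene, fell from 90.8 ± 3.90 to 51.1 ± 3.98 CPM (adjusted p 0.00856). The unpaired test gave 0.258 for TNFRSF11B, 0.258 for ICAM1 and 0.163 for THOP1.

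**Figure D2:**
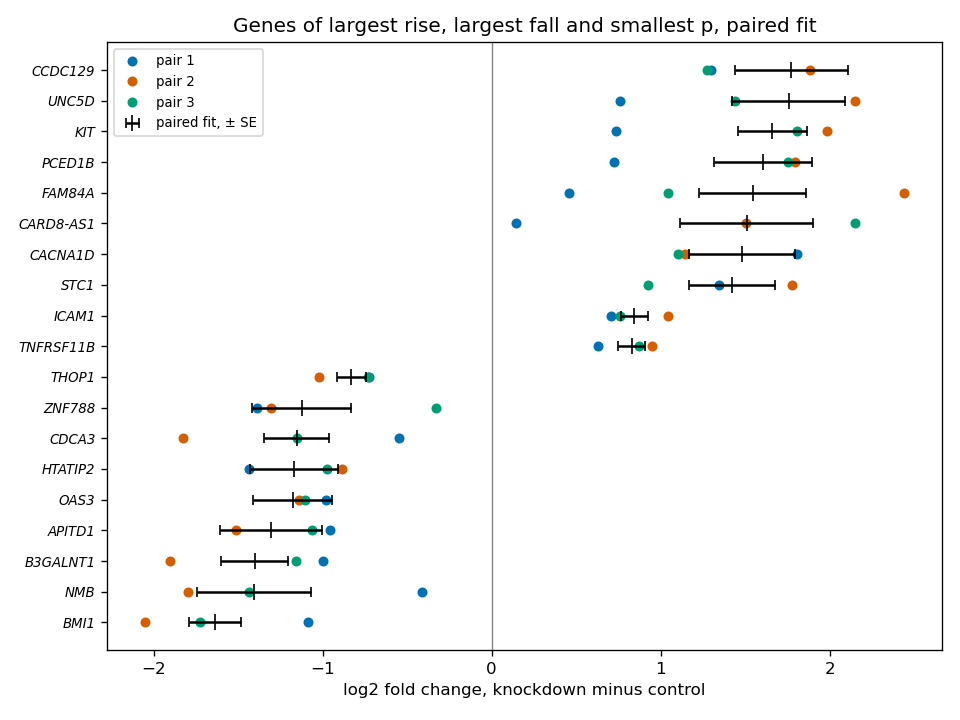
Log2 fold change (x axis, knockdown minus control) of the genes of largest rise, largest fall and smallest p in the paired fit, with points for the 3 pairs and black marks for the fitted value ± SE. Low-count genes lie closer to 0 in the points than in the fit because the points carry a prior count of 2.

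Genes of the cell division cycle were lower in knockdown. Members of the G1/S and S phase list fell with a median log2 fold change of -0.60 (40 genes, camera adjusted p 3.23e-15), and those of the G2/M list with a median of -0.62 (45 genes, camera adjusted p 4.39e-16). With an estimated correlation both calls were lost (camera adjusted p = 0.742, and 0.686 in the paired fit). The estimated correlations between members were 0.936 and 0.953 in the unpaired fit. Lists with lower values lost their calls too, such as the BMP and TGF-beta list (0.245). In the paired fit 34 of the 40 G1/S and S phase genes and 41 of the 45 G2/M genes were lower and none was higher, together 10.8% of all genes called lower. Adjusted over the list alone the unpaired test called 23 and 14, and the paired fit 36 and 45. The replication licensing factor gene CDT1 changed by -0.78 (SE 0.126), the checkpoint mediator gene CLSPN by -0.96 (SE 0.16) and GINS2 by -0.70 in the paired fit. MKI67, the gene of the proliferation antigen, went from 382.7 ± 41.0 to 214.6 ± 73.1 CPM (n = 3 each), with a log2 fold change of -0.88 (SE 0.141). TACC3 changed by -0.74 and the phosphatase gene CDC25B by -0.41. The median over both lists was -0.28 in pair 1, -1.14 in pair 2 and -0.55 in pair 3. Without knockdown library 2 the unpaired medians were -0.40 and -0.38.

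Inhibitors of cyclin-dependent kinases moved the other way in the paired fit. Of 6 tested members, CDKN1A (p21), CDKN1C (p57) and CDKN2B (p15) rose, by 0.48, 0.59 and 0.79 on the log2 scale. The list passed in the paired fit (camera adjusted p 0.0412) but not in the unpaired one (0.128), and the paired call was lost with an estimated correlation (adjusted p = 0.686). Without pair 2 the paired p was 0.0707 at a median of 0.39, and without pair 3 it was 0.240 at a median of 0.26. The unpaired median was 0.34 without knockdown library 2 and 0.31 without knockdown library 3. The paired p was 0.154 with no filter on low counts, at a paired median of 0.26 in place of 0.53, and 0.131 with at least 1 CPM in 3 libraries. CDKN2A, the INK4A and ARF locus repressed by BMI1 in many cell types, had 4.34 ± 1.06 CPM in control and 6.34 ± 2.29 CPM in knockdown libraries (n = 3 each). Its edgeR adjusted p was 0.452, and 0.181 in the paired fit, with log2 differences of -0.28, 0.58 and 1.14 in the 3 pairs. CDKN2B had 4.96 ± 2.58 and 8.59 ± 4.55 CPM, with log2 differences of 0.67, 0.79 and 0.77 (paired adjusted p 0.0330).

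Genes regulated by p53 rose with a median log2 fold change of 0.22 (31 genes, camera adjusted p 0.000649), a call lost with an estimated correlation (adjusted p = 0.742). In the paired fit 8 members rose, among them the death receptor gene TNFRSF10B (0.50), ZMAT3 (0.73) and CDKN1A, and 1 fell, the DNA repair gene XPC (-0.61). Without knockdown library 2 the median was 0.12 (camera adjusted p 0.0275). The list of secreted factors associated with senescence rose with a median of 0.39 (18 genes, camera adjusted p 0.00201), also lost with an estimated correlation (adjusted p = 0.742). In the paired fit 8 of these rose and 1 fell: the urokinase gene PLAU rose by 0.67, its receptor gene PLAUR by 1.22 and the protease inhibitor gene SERPINE2 by 0.52. The member that fell was the growth factor-binding protein gene IGFBP5 (-0.32), named after its value was seen. Without knockdown library 3 the camera adjusted p was 0.0622 at a median of 0.29. The median was 0.67 without knockdown library 1 and 0.59 without control library 3.

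Genes of the BMP and TGF-beta pathways rose with a median log2 fold change of 0.43 (25 genes, camera adjusted p 0.0185). This call was lost with an estimated correlation (adjusted p = 0.742). In the paired fit 6 members rose, among them the BMP antagonist gene GREM1 (1.32) and the receptor genes TGFBR2 (0.66) and BMPR2 (0.58), and 1 fell, the activin antagonist gene FST (-0.44). The camera adjusted p was 0.111 without control library 1, 0.123 without knockdown library 2 and 0.0622 without knockdown library 3, at medians of 0.23, 0.16 and 0.22. Mesenchymal and fibroblast markers rose with a median of 0.27 (17 genes, camera adjusted p 0.0185; adjusted p = 0.742 with an estimated correlation). The extracellular matrix genes POSTN (0.31), SPARC (0.34), COL3A1 (0.39) and COL5A1 (0.41) were the 4 members that rose in the paired fit. Without knockdown library 2 the median of this list was 0.03 (camera adjusted p 0.245) and the unpaired value of COL5A1 was -0.033. Its camera adjusted p was 0.0943 without control library 1 (median 0.16) and 0.0594 without control library 3, and the median was 0.43 without knockdown library 1.

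Cytosolic ribosomal protein genes rose by a median of 0.20 (71 genes, camera adjusted p 5.33e-11; adjusted p = 0.742 with an estimated correlation). In the paired fit 9 rose, among them RPL34 (0.32), RPL15 (0.30) and RPS19 (0.28), and none fell; these genes have many near-identical pseudogenes, so their counts are uncertain. The median was 0.11 without knockdown library 1. Cholesterol synthesis genes fell with a median of -0.29 (25 genes, camera adjusted p 0.000629; adjusted p = 0.742 with an estimated correlation), and 3 fell in the paired fit: SC5D (-0.54), HSD17B7 (-0.55) and MVD (-0.52). The pair medians were -0.09, -0.76 and -0.14, and without knockdown library 2 the unpaired median was -0.10 (camera adjusted p 0.236). Clustered protocadherins, neuronal adhesion molecules, had a median of 0.25 (37 genes, camera adjusted p 0.0496; adjusted p = 0.742 with an estimated correlation). In the paired fit 5 rose, among them PCDHB14 (0.66), PCDHB10 (0.66), PCDHA4 (0.47) and PCDHA12 (0.88). PCDHA4 and PCDHA12 share exon sequence with each other and with the other PCDHA genes. The list passed in the paired fit (camera adjusted p 0.00972), but not without pair 2 (camera adjusted p 0.302 at a paired median of 0.07). The pair medians were -0.11, 0.62 and 0.14, and without knockdown library 2 the unpaired median was -0.17 (camera adjusted p 0.778), with PCDHA12 at -0.30. The camera adjusted p was 0.111 without control library 1, 0.305 without control library 3, 0.0629 with RLE size factors and 0.0665 with no filter.

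**Figure D3:**
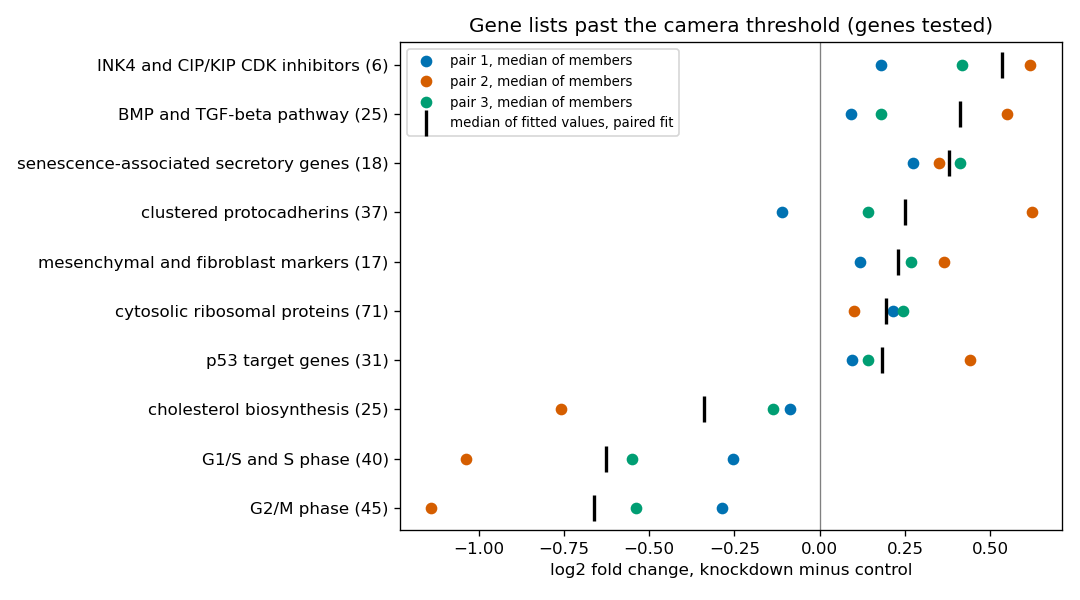
Median log2 fold change (x axis, knockdown minus control) of the 10 gene lists past the camera threshold with the preset correlation in the unpaired or the paired fit, with the number of genes tested in brackets. Points are medians within each pair and black bars medians of the paired fit. Pair 2 lies farthest from 0 for 8 of the 10 lists, among them the cell cycle (-1.04 and -1.14) and cholesterol (-0.76) lists, and pair 1 lies below 0 for the protocadherins.

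The remaining 20 lists did not pass in either fit. The paired fit called 1296 of the 12937 genes tested, so a few called members in a short list are no sign that the list itself shifted. None of 24 other Polycomb repressive complex 1 subunits passed in the paired fit (median -0.04), with PCGF5 at -0.24 (adjusted p 0.0785) and PCGF6 at -0.37 (adjusted p 0.0944). Of 11 Polycomb repressive complex 2 subunits, the methyltransferase gene EZH2 fell by 0.51 (paired adjusted p 0.0288), and PHF19 was at -0.32 (adjusted p 0.0521). In the COMMD and commander complex list 1 of 15 genes passed, DSCR3 (-0.39). Only 2 of 39 HOX genes had enough counts to be tested, HOXB2 and HOXB3, too few for a list test; all HOX genes together had 113, 211 and 71 counts in control and 91, 261 and 89 counts in knockdown libraries. Of 11 tested developmental regulators of non-neural tissues only MSX1 rose (1.16, paired adjusted p 0.0425).

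Markers of neural cell types moved in both directions in the paired fit. Of 23 neural stem cell markers NOTCH2 (-0.42) and PLAGL1 (-0.26) fell and MMRN1 (0.30) rose; reads of NOTCH2 and the near-identical NOTCH2NL could have been split or dropped. Of 15 neuronal markers, ELAVL3 (-0.96), NEFM (-0.89) and DPYSL3 (-0.58) fell and NHLH2 (1.20) rose. Of 11 astroglial markers SPARCL1 (0.52), TNC (0.49), GJA1 (0.26) and APOE (0.25) rose and none fell (camera adjusted p 0.305, paired 0.365). None of 10 oligodendrocyte lineage markers passed, 2 of 12 neural crest markers rose (ITGA4 at 1.09 and SNAI1 at 0.42), and 2 of 10 endothelial markers rose (CDH5 at 0.55 and TIE1 at 0.45). None of 5 pluripotency markers passed. In the signalling lists, the Hedgehog receptor and target gene PTCH1 fell by 0.59 (SE 0.077, paired adjusted p 0.0187) and GLI2 by 0.26, of 11 tested. In the WNT list of 21, DKK3 (0.70), DKK2 (0.66) and SFRP1 (0.30) rose and SFRP2 (-0.28) fell. In the Notch list of 17, HES6 (-0.78) fell beside NOTCH2.

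Metabolic and stress lists showed few changes in the paired fit. None of 28 antioxidant genes and none of 44 nuclear genes of oxidative phosphorylation passed. Of 31 glycolysis and hypoxia genes P4HA1 (0.33) and SLC2A1 (0.24) rose and HK2 (-0.54) and LDHA (-0.38) fell. Of 24 genes of the unfolded protein and integrated stress responses TRIB3 (-0.85) and PSPH (-0.40) fell and VLDLR (0.45) rose. Of 20 interferon response genes OAS3 alone passed, and none of 6 replication-dependent histone genes did. The median, mean and test direction of the pluripotency, Notch, glycolysis and stress response lists differed in sign in the unpaired fit, and those of the pluripotency, antioxidant and glycolysis lists in the paired fit.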

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

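The alternatives of the paired fit were chosen after the data were seen; those of the unpaired fit were planned. The fall of BMI1 kept its direction and its call, adjusted over the list alone, under all 12 alternatives, at -1.87 to -1.44. The unpaired count of 0 genes rose to 2 with no filter (BMI1 and THOP1), 150 with DESeq2 and 1296 with the replicate block; leaving out 1 library gave 0 to 665, the highest without knockdown library 1. The paired count of 1296 became 2171 with no filter, 592 with DESeq2 (586 of them shared), 12 at an adjusted p of 0.01 and 77 with a minimum log2 fold change of 1; leaving out 1 pair gave 912 to 2296, the highest without pair 2. Of the 9 lists called unpaired and the 10 called paired, 0 passed with an estimated correlation and 0 with fry (smallest fry adjusted p of these lists 0.502, paired 0.203). Leaving out 1 library gave 6 to 10 called lists. Over the 6 fits without 1 library, the protocadherin median ran from -0.17 to 0.40, COL5A1 from -0.033 to 0.78 and PCDHA12 from -0.30 to 1.89; the negative values came without knockdown library 2, and the cause was not tested. Other named genes kept their direction in the unpaired alternatives. Adjusted over all genes, edgeR called no gene without the block, while 91 of the 98 named genes passed with it. Many of these are given above with the paired result alone. Among the lists, the block added only the call of the inhibitors of cyclin-dependent kinases. With total counts of 4962745 to 9640349 per library, genes of a few CPM rest on few reads.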

Other observations

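At the stricter adjusted p of 0.01 the paired edgeR fit called 12 genes. Those not described above, named here after their values were seen, were TM4SF18 (1.25 on the log2 scale), MAMDC2 (1.00), NDRG4 (0.93) and the sodium pump subunit gene ATP1B1 (0.64) among the higher, and the ribosome assembly factor gene EBNA1BP2 (-1.12) and the decapping enzyme gene DCP2 (-0.70) among the lower.

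The tests of single pairs and of knockdown libraries 1 and 3 and every test of a 3' UTR match other than the first scan were chosen after the results they bear on were seen. The 6 libraries can be split 3 against 3 in 10 ways. The unpaired test called 0 genes in the real split, and the highest of the other splits was 0, so 10 of the 10 splits gave as many. Any split gives at least 0 genes, so this comparison could not decide anything. Of the 4 splits that part all 3 pairs, the real one gave 1296 genes in the paired fit, and the highest of the other 3 gave 0; each of these others moves 1 pair to the opposite side. Both sets of splits are too few for a share under 0.05.

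Cell cycle genes were lower in all 3 pairs, by different amounts (medians of -0.28 and -0.55 in pairs 1 and 3, with 79 and 85 of the 85 genes below 0). With every library thinned to the smallest total, the median of the 85 genes in the paired fit was -0.643. Random thinning leaves the expected ratios between libraries unchanged, so this value could hardly have moved and decides nothing about depth. With a trend in GC content and transcript length removed the median was -0.636, which argues against that trend. The trend had little room to act, as these genes lie near all tested genes in median GC content (45.9 against 48.2%) and length (3240 against 3512.5 bases). Without pair 2 the paired fit still called 79 genes lower (list medians -0.42 and -0.44), which goes against knockdown library 2 alone, but these genes move together, and with 1 median per library knockdown libraries 1 and 3 differed from the controls by -0.39 (95% interval -1.01 to 0.22; that over the 2 pair medians, used first, was wider), so with so few libraries knockdown library 2 alone cannot be told apart. Direct pairing of a hairpin with the 3' UTR sequence AAAGGA cannot account for most of the set: 53 of the 75 genes called lower lack it, and 29.3% carry it (95% Wilson interval 20.2 to 40.4%; the bound of 50% replaced a comparison with the 49.7% of all genes searched, not matched for UTR length, after the share was seen, and either gives the same label). Pair 2 also had the largest fall of BMI1 (-2.05, against -1.09 in pair 1 and -1.73 in pair 3), and 3 pairs are too few to test this order. Effects of lowered BMI1, indirect hairpin effects and culture density were not tested and stay open.

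The 3' UTRs of the genes called lower in the paired fit were searched for short sequences in excess. The labels name a hairpin for the control only and give no hairpin sequence. UTRs were available for 95.6% of the 697 lower genes, and shares were compared with other tested genes of like UTR length. The 7-mer AAAGGAA led, in 40.1% of lower and 30.4% of other genes, an excess of 11.3 percentage points after length matching (95% interval 7.93 to 14.7, adjusted p 3.75e-07 over 16384 7-mers). TAAAGGA followed with 8.35 points. Both are parts of TAAAGGAA, and 9.20% of the 1011 genes with that 8-mer were lower, against 3.26% of genes of like UTR length without its inner 6-mer. One annotated BMI1 transcript, of 3428 bases, holds TAAAGGA at position 1104, upstream of its 3' UTR, and at position 3048, within it. The whole 8-mer was not found in this transcript. TAAAGGA lies in the 3' UTR of 18.2% of the genes not called lower. BMI1 was itself among the lower genes scanned, so this match is not independent evidence. Of the 20 lower genes of smallest p other than BMI1, 9 carry the 8-mer, PTCH1, B3GALNT1, EBNA1BP2 and DCP2 among them, where 8.71% of all searched genes do; the site was picked from these genes, so this share and that of 9.20% are not independent evidence. Among higher genes the leading 7-mer was TTTGCAC (excess 9.21 points, adjusted p 0.00318).

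An off-target effect of the hairpin through a seed match is a candidate explanation for part of these falls, and the tests did not settle it. A single match acting in most lower genes is argued against: if the lower genes it does not act on carry it as often as other genes of like UTR length, no 6-mer or 7-mer could account for more than 27.2% of them, upper 95% bounds included (this replaced a fixed bound of 50 points of excess, set before the scan, which overlooked how common a match is in other genes). That condition is doubtful for AAAGGA, carried by 29.3% of the 75 lower cell cycle genes and 60.9% of the other 591 lower genes. Its share in all searched genes was 49.7%, and these shares are not matched for UTR length. The bound may thus be too low for this match. For a match in part of them, the 8-mer was first ranked among all 168 orders of its bases, where it came 3rd by excess of lower genes (4.38 points, highest other 5.12, ATAAAGGA, which contains TAAAGGA). The comparison was then repeated without the orders that share 6 bases in a row with it, and it came first of 158 (highest other 3.37); this second version was adopted after the first was seen, and both are circular because the site was picked from the same genes. A last test divided the genes at random into 2 equal parts, picked the leading 7-mer in one and measured it in the other. One part picked AAAGGAA, whose held-out excess was 9.93 points (5.32 to 14.5), rank 2 of 16384 7-mers (one-sided normal test, unadjusted p 1.21e-05). The other picked TGTATTT, whose held-out excess was 4.11 points (-0.44 to 8.66). The condition set, a lower bound above 0 both ways, was therefore not met. The direction that failed measured TGTATTT and does not bear on AAAGGAA. Both parts come from the same 6 libraries.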
